A study of Mus musculus with 9 samples.

How the data were processed

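Messenger RNA of left ventricular tissue was sequenced from 9 mouse samples in 3 groups of 3. Per the labels' protocols, polyadenylated RNA was selected and made into directional libraries that were read from both ends on an Illumina NovaSeq. Per the submitters' processing notes, HISAT2 and DESeq2 were used, with no version or role given, and the build is named GRCh38, a human build. The symbols and coordinates of the table are mouse, and 25482 of its 30128 genes have spans identical to the GENCODE M21 annotation of GRCm38, so positions are given on GRCm38. The counting program and its strand setting are not given in the sources used here. 26 symbols had been turned into dates and were left as they stand.

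The deposited table holds RPKM values, reads per kilobase of gene length, scaled to a common total of counted reads, for 30128 genes in 9 columns, with gene length beside them. The unit was read from the values: each deposited RPKM value times gene length is a whole multiple of 1 step per library for 99.9839% of the values above 0, within a tolerance of 0.01 reads. The step gave the reads behind each value and the depth of each library (56497662, 42084137 and 52133850 reads in control, 35970332, 37945110 and 42370259 with null virus, 50512862, 41055880 and 48619435 with USP28 virus). The design fixed before the data were examined assumed counts and a quasi-likelihood test on them. Since the table holds RPKM, limma was used in its place, and camera ran on the same log2 values. The fixed filter, filterByExpr for counts, was replaced by a threshold on RPKM. The fixed rules for comparisons, gene lists and named genes were otherwise kept.

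RPKM values were scaled with a trimmed mean of M values, trimming 30% of the ratios and 5% of the levels, and log2(scaled RPKM + 0.1) was tested in limma 3.58.1 (R 4.3.3) with a trended, robust prior. Fold changes are on that scale, which understates the change of low genes. Genes with RPKM of at least 0.5 in at least 3 libraries were kept, 14104 in all. All 9 libraries entered 1 fit with 3 groups and no covariate, so the 3 comparisons share 1 estimate of the spread. P-values were adjusted by Benjamini-Hochberg within each comparison, and genes under 0.05 are said to have passed, risen or fallen. Levels are means ± SD of scaled RPKM over 3 libraries. Usp28 was also compared by an exact permutation test.

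By the same design, 34 pathway lists and 16 cell type marker lists were set, with 6 members that matched no symbol of the table. The 48 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01 and adjusted over 144 tests. It was repeated with an estimated correlation, which left 0 calls in each comparison. The fry test, which asks whether a list's genes move on balance in 1 direction and makes no comparison with other genes, was also run. Named genes followed a rule fixed beforehand. They were 11 genes of interest and the 8 largest rises and falls with non-overlapping groups and a mean of at least 2 CPM. Up to 3 members of each list with a member past the threshold were added. So were the 8 genes with the strongest opposite calls in both comparisons that share the null-virus libraries. Gene models and pseudogenes were left out of the largest changes by that rule, and of these 8 beyond it. The 11 genes with values that are not whole reads were singled out after their values were seen.

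The libraries were compared before averaging. No pair of a group held identical values, and chi-square per degree of freedom was 20.8 to 160, with the highest values, 130 and 160, in the pairs of null-virus replicate 1. On reads simulated for all genes with the spread of the real libraries and known changes in some, the fit for null virus against control recovered 50.8% of genes changed 2-fold and 83.1% of those changed 3-fold among 14169 tested, with 3 of 13956 unchanged genes called. For USP28 virus against null virus it recovered 54.7% and 76.6% among 14245, with 12 of 14031 unchanged genes called. For USP28 virus against control it recovered 52.2% and 85.5% among 14260, with 11 of 14049 called. Genes changed 1.5-fold were recovered at 6.2%, 12.1% and 12.9% in the same order. The simulated genes were independent, with a spread pooled by expression level and equal in all libraries. No simulated library stood apart as null-virus replicate 1 does, so these rates may not hold for the real comparisons.

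Alternatives were other scalings (median of ratios, library totals alone), filters and thresholds, fits of 2 groups alone, the replicate number as a block, limma voom on the recovered reads, mitochondrial genes left out, and each library left out in turn. Pseudocounts of 1 and 0.01, the removal of gene length and GC trends with splines of 4 degrees of freedom, the omission of values that are not whole reads, and library totals for the lists were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.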

Results

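The data were gene-level expression values of 9 left ventricle RNA libraries from mice, in 3 groups of 3. The control group was wild type, with no virus given in the labels. Both other groups were db/db mice, which carry a mutation of the leptin receptor gene Lepr and become obese and diabetic. One db/db group had received an empty adeno-associated virus of serotype 9, a vector that reaches the heart (null virus). The other had received the same serotype carrying USP28, a deubiquitinating enzyme, under the cardiac troponin T promoter, which is active in cardiomyocytes (USP28 virus). The stated purpose was to learn what USP28 overexpression does in the failing and remodelling diabetic heart. Depth, as recovered from the values, was between 35970332 and 56497662 reads per library. Mitochondrially encoded genes took 15.7% to 19.9% of them. A gene listed at 0 could hold up to 3 reads, which is 0.053 to 0.083 CPM by library and covers counting error only. The labels do not say that the libraries of a group come from separate animals, so the p-values measure the spread between these samples. Coordinates are those of the deposited table and match the mouse build GRCm38.

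Usp28 was measured first, since it bears on the labels. The gene lies on chromosome 9 at 48985375 to 49042517. Its scaled RPKM was 12.5, 13.3 and 13.8 in control replicates 1, 2 and 3, then 9.92, 7.51 and 7.82 in the null-virus libraries, and 9.95, 11.3 and 11.3 in the USP28-virus libraries. Usp28 fell by 0.65 on the log2 scale between control (13.2 ± 0.661, SD, n = 3) and null virus (8.42 ± 1.31), with SE 0.12 and adjusted p = 0.0073. Between null virus and USP28 virus (10.8 ± 0.774) the log2 difference was 0.37 (SE 0.12, adjusted p = 0.18), a mean of 129% of the null-virus mean that did not pass the test. Against control the USP28-virus libraries were at a log2 difference of -0.28 (adjusted p = 0.16). Exact two-sided permutation tests gave p = 0.1 in each comparison, the smallest p that 3 against 3 allows. Whether reads of the viral USP28 sequence were counted under this gene is not given in the sources used here. Lepr was at 0.148 ± 0.11 scaled RPKM in control, 0.188 ± 0.0315 with null virus and 0.206 ± 0.0349 with USP28 virus, under the filter, and was not tested.

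**Figure D1:**
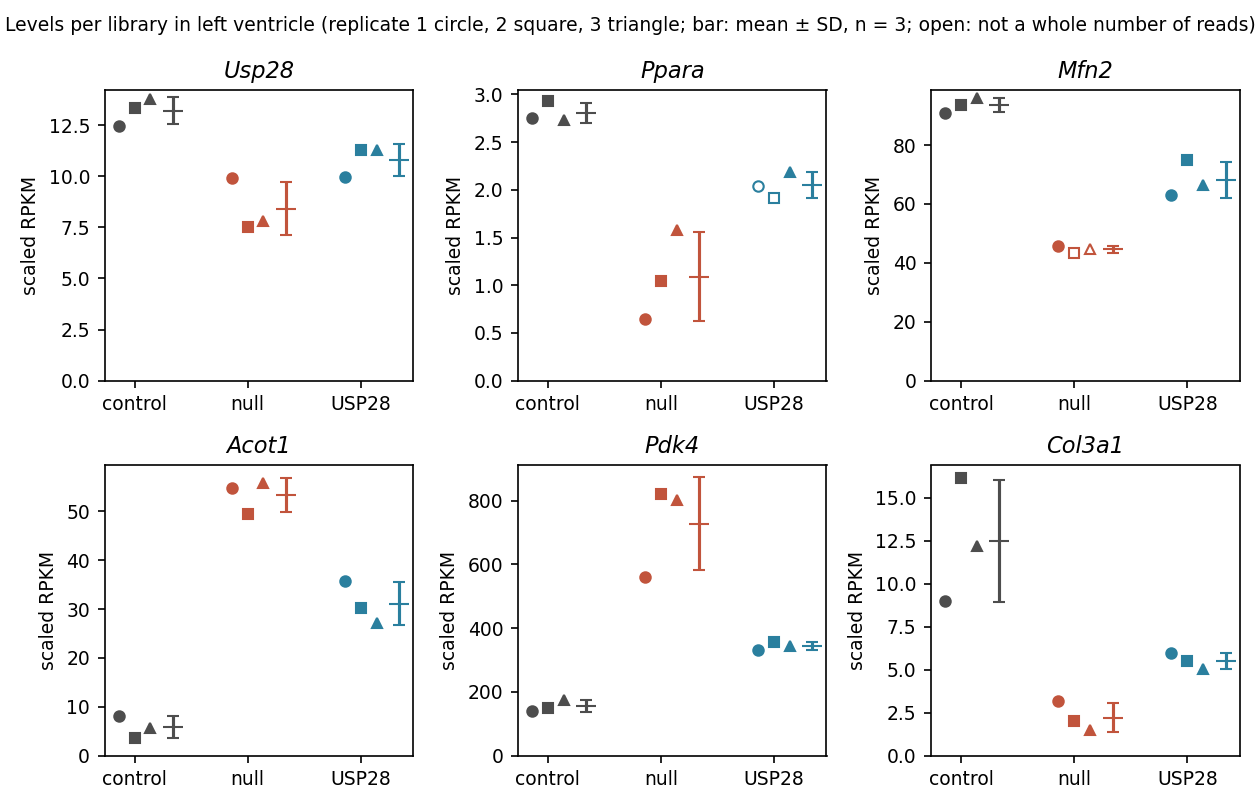
Scaled RPKM of 6 genes in each library, with the group mean and SD beside the 3 points of each group and open points for values that are not a whole number of reads. Usp28 was 13.2 in control, 8.42 with null virus and 10.8 with USP28 virus, and Acot1 was 5.78, 53.3 and 31.1.

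The comparison of db/db hearts given null virus with control hearts addresses what diabetes and the empty virus together do to the ventricle, since the design does not part genotype from virus. The labels give no strain, so a strain difference between db/db and control mice would enter here too. Acot1, Pdk4 and Cat were among the genes higher in the db/db hearts, and Col3a1, Actc1, Mfn2 and Opa1 among those lower. Acot1, a cytosolic acyl-CoA thioesterase (chromosome 12, 84009502 to 84017670), rose from 5.78 ± 2.24 to 53.3 ± 3.44 scaled RPKM (SD, n = 3), a log2 change of 3.25 (SE 0.25, adjusted p = 0.00047). Pdk4, the kinase that switches off pyruvate dehydrogenase (chromosome 6, 5483351 to 5496309), rose from 155 ± 18.1 to 727 ± 146 (log2 2.21, adjusted p = 4e-04). Col3a1, a fibrillar collagen (chromosome 1, 45311538 to 45349706), was 12.5 ± 3.57 in control and 2.22 ± 0.87 in db/db hearts (log2 -2.46, adjusted p = 0.0012). Of 14104 genes tested, 3152 passed, 1421 higher and 1731 lower. Groups did not overlap for 5817 genes (41.2%, against 10% by chance). The number passing was 1445 without control replicate 2 and 1474 without control replicate 3, and 1673 in a fit of the 2 groups alone. Of the 459 genes in the lists that camera called here, 175 passed, and 119 to 239 did so when 1 library was left out.

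The PPAR alpha target list, genes switched on by the fatty acid receptor PPAR alpha, had 13 of 18 measured members higher and 0 lower (16 higher adjusted over the list alone; camera adjusted p = 2.6e-10, and adjusted p = 0.33 with an estimated correlation). Besides Acot1 and Pdk4 these included Acot2, the mitochondrial counterpart of Acot1 (log2 2.12). Acot1 and Acot2 are near-identical neighbouring genes, so the division of reads between them is uncertain. Of the fatty acid beta-oxidation list 13 of 22 members rose and 0 fell (14 higher adjusted over the list alone; adjusted p = 2.4e-06, and adjusted p = 0.39 with an estimated correlation). Decr1, which handles unsaturated fatty acids, rose by 1.16 and Eci2, an enoyl-CoA isomerase, by 0.91 on the log2 scale. Among lipid storage and lipogenesis genes 9 of 25 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.023, and adjusted p = 0.38 with an estimated correlation). They included Pnpla2, the adipose triglyceride lipase (log2 1.47), Cidea, a lipid droplet protein (log2 1.46), and Plin2, which coats lipid droplets (log2 0.82). Of 28 antioxidant genes 10 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 8.5e-05, and adjusted p = 0.38 with an estimated correlation). They included Cat, which encodes catalase (163 ± 16.1 against 63.6 ± 5.21, log2 1.35), Ucp2, a mitochondrial carrier (log2 1.95), and Gstm1, a glutathione transferase (log2 0.75).

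Single genes of ketone use and of glucose entry went the other way. Oxct1, the enzyme that activates ketone bodies for oxidation, was at 103 ± 20.9 against 311 ± 11.4 (log2 -1.62, adjusted p = 0.00092), and Bdh1, which oxidises beta-hydroxybutyrate, fell by 1.96 (adjusted p = 0.0016). Hk2, the insulin-regulated hexokinase, fell by 1.54 (adjusted p = 0.00067), within a glycolysis list of which 1 of 26 members rose and 7 fell (1 and 9 adjusted over the list alone; adjusted p = 0.068, and adjusted p = 0.65 with an estimated correlation). Without null-virus replicate 1 the glycolysis list had 14 members lower and 3 higher (adjusted p = 0.0047), and with length and GC trends removed its adjusted p was 0.018. Of 22 genes of branched-chain amino acid breakdown 9 fell and 0 rose (12 lower and 1 higher adjusted over the list alone; adjusted p = 0.0084, and adjusted p = 0.39 with an estimated correlation). They included Dbt, a subunit of the branched-chain ketoacid dehydrogenase (log2 -0.66), and Ivd, isovaleryl-CoA dehydrogenase (log2 -0.63).

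Mitochondrial fusion and fission genes had 5 of 17 members lower and 0 higher (6 lower adjusted over the list alone; adjusted p = 0.0011, and adjusted p = 0.35 with an estimated correlation). Mfn1 and Mfn2, the mitofusins that join outer membranes, were at 23.7 ± 1.73 against 55.5 ± 1.08 (log2 -1.23, adjusted p = 4e-04) and at 44.6 ± 1.1 against 93.5 ± 2.41 (log2 -1.07, adjusted p = 0.00058). All 3 null-virus values of Mfn1 and 2 of those of Mfn2 were not whole numbers of reads. Without them Mfn1 could not be tested. Mfn2 was at log2 -1.03, with null-virus replicate 1 as the only library left in its group. Opa1, the inner membrane fusion protein, fell by 1.01 on the log2 scale (adjusted p = 0.00075). Of 17 regulators of mitochondrial biogenesis 8 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.0097, and adjusted p = 0.39 with an estimated correlation). Ppara, which encodes PPAR alpha itself (chromosome 15, 85734983 to 85802819), was at 1.09 ± 0.469 against 2.81 ± 0.105 (log2 -1.37, adjusted p = 0.0071), and Ppargc1b, a coactivator of mitochondrial genes, fell by 1.10. Nuclear-encoded subunits of oxidative phosphorylation had 5 of 76 members higher and 1 lower (0 adjusted over the list alone), with a median log2 change of 0.39 (adjusted p = 5.7e-06, and adjusted p = 0.66 with an estimated correlation). That median was 0.11, with 15 higher and 1 lower, without null-virus replicate 1, a library whose mean absolute departure from its group was 0.501 on the log2 scale, against 0.216 to 0.32 in the other libraries. Mitophagy and autophagy genes had 8 of 27 members higher and 2 lower (13 and 3 adjusted over the list alone; adjusted p = 0.026, and adjusted p = 0.48 with an estimated correlation). There were rises in Bnip3, a mitophagy receptor (log2 1.01), Gabarapl1, an autophagosome protein (log2 0.99), and Pink1, the kinase that marks damaged mitochondria (log2 0.53).

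The extracellular matrix list had 19 of 33 members lower and 0 higher (22 lower and 1 higher adjusted over the list alone; adjusted p = 5.6e-08, and adjusted p = 0.38 with an estimated correlation). Col15a1, a basement membrane collagen (log2 -2.09), Col6a3, a microfibrillar collagen (log2 -1.91), Lum, the proteoglycan lumican (log2 -1.31), and Col1a1, the main fibrillar collagen (log2 -0.82), were among them. Beside this, 6 of 13 fibroblast markers were lower and 1 higher (6 and 1 adjusted over the list alone; adjusted p = 0.15), and Lum and Col1a1 stand in both lists. Contractile and calcium handling genes had 8 of 22 members lower and 0 higher (10 lower adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.39 with an estimated correlation). Actc1, cardiac actin, was at 563 ± 169 against 1710 ± 82.3 (log2 -1.64), and Casq2, the calcium store of the sarcoplasmic reticulum, fell by 0.89. Of the ion channel list 7 of 20 members fell and 1 rose (10 and 2 adjusted over the list alone; adjusted p = 0.014, and adjusted p = 0.53 with an estimated correlation). Gja1, the gap junction protein connexin 43, was among those that fell (log2 -1.27). The ion channel list had adjusted p = 0.13 without null-virus replicate 1. The natriuretic peptide and fetal gene list had 5 of 17 members lower and 2 higher (6 and 3 adjusted over the list alone; adjusted p = 0.29). Xirp2, an actin-binding protein of the intercalated disc, was lower (log2 -1.12), and Ctgf, connective tissue growth factor (log2 1.68), and Uchl1, a deubiquitinating enzyme (log2 0.97), were higher. Nppa, atrial natriuretic peptide (adjusted p = 0.81), and Myh7, beta myosin heavy chain (0.16), did not pass. Neither did Nppb, B-type natriuretic peptide (log2 -2.43, adjusted p = 0.18), or Myh6, alpha myosin heavy chain (log2 -0.39, adjusted p = 0.1). Nppb was at 160, 3.48 and 15.5 in null-virus replicates 1, 2 and 3, against 146 ± 96.9 in control. Without null-virus replicate 1, Nppb (log2 -3.90, adjusted p = 0.016) and Myh6 (log2 -0.52, adjusted p = 0.0085) passed. Contractile genes had 14 lower and 1 higher when null-virus replicate 1 was left out.

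Glucocorticoid targets had 11 of 15 members higher and 0 lower (13 higher adjusted over the list alone; adjusted p = 2.8e-08, and adjusted p = 0.33 with an estimated correlation). Nfkbia, the inhibitor of NF-kappa B (14.1 ± 0.345 against 6.16 ± 0.185, log2 1.19), Sult1a1, a sulfotransferase (log2 1.45), and Cdkn1a, the cell cycle inhibitor p21 (log2 1.24), were among them. Pdk4 is a member of this list too. Interferon response genes had 8 of 25 higher and 0 lower (11 and 1 adjusted over the list alone; adjusted p = 0.00023, and adjusted p = 0.53 with an estimated correlation). Irf7 led them, a transcription factor of the interferon response (log2 1.56). Antigen presentation genes had 10 of 18 higher and 0 lower (11 higher adjusted over the list alone; adjusted p = 0.00033, and adjusted p = 0.48 with an estimated correlation). H2-Q4, H2-T23 and H2-D1, class I major histocompatibility genes whose similar copies make read assignment uncertain, were at log2 1.20, 1.15 and 0.88. Endothelial markers had 4 of 14 higher and 0 lower (6 higher adjusted over the list alone; adjusted p = 0.0045, and adjusted p = 0.39 with an estimated correlation). They included the junction genes Cldn5 (log2 1.44) and Esam (log2 0.85). Macrophage markers had 3 of 12 lower and 0 higher (3 lower adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.53 with an estimated correlation). They included Cx3cr1, the fractalkine receptor (log2 -1.49). The macrophage list had adjusted p = 0.12 without null-virus replicate 1. Heat shock genes had 7 of 20 lower and 0 higher (9 lower adjusted over the list alone; adjusted p = 0.00033, and adjusted p = 0.53 with an estimated correlation). Stip1, an HSP70 and HSP90 co-chaperone, was at log2 -1.19 and Hspa4l, an HSP110 family chaperone, at -1.13. Of the genes of the integrated stress response 8 of 15 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 0.0077, and adjusted p = 0.35 with an estimated correlation). They included Mthfd2, a mitochondrial folate enzyme (log2 1.54), and Ddit4, an inhibitor of mTORC1 (log2 1.51). Leaving out null-virus replicate 1 gave 16 higher interferon genes, 10 higher and 1 lower endothelial markers, and 12 lower heat shock genes.

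**Figure D2:**
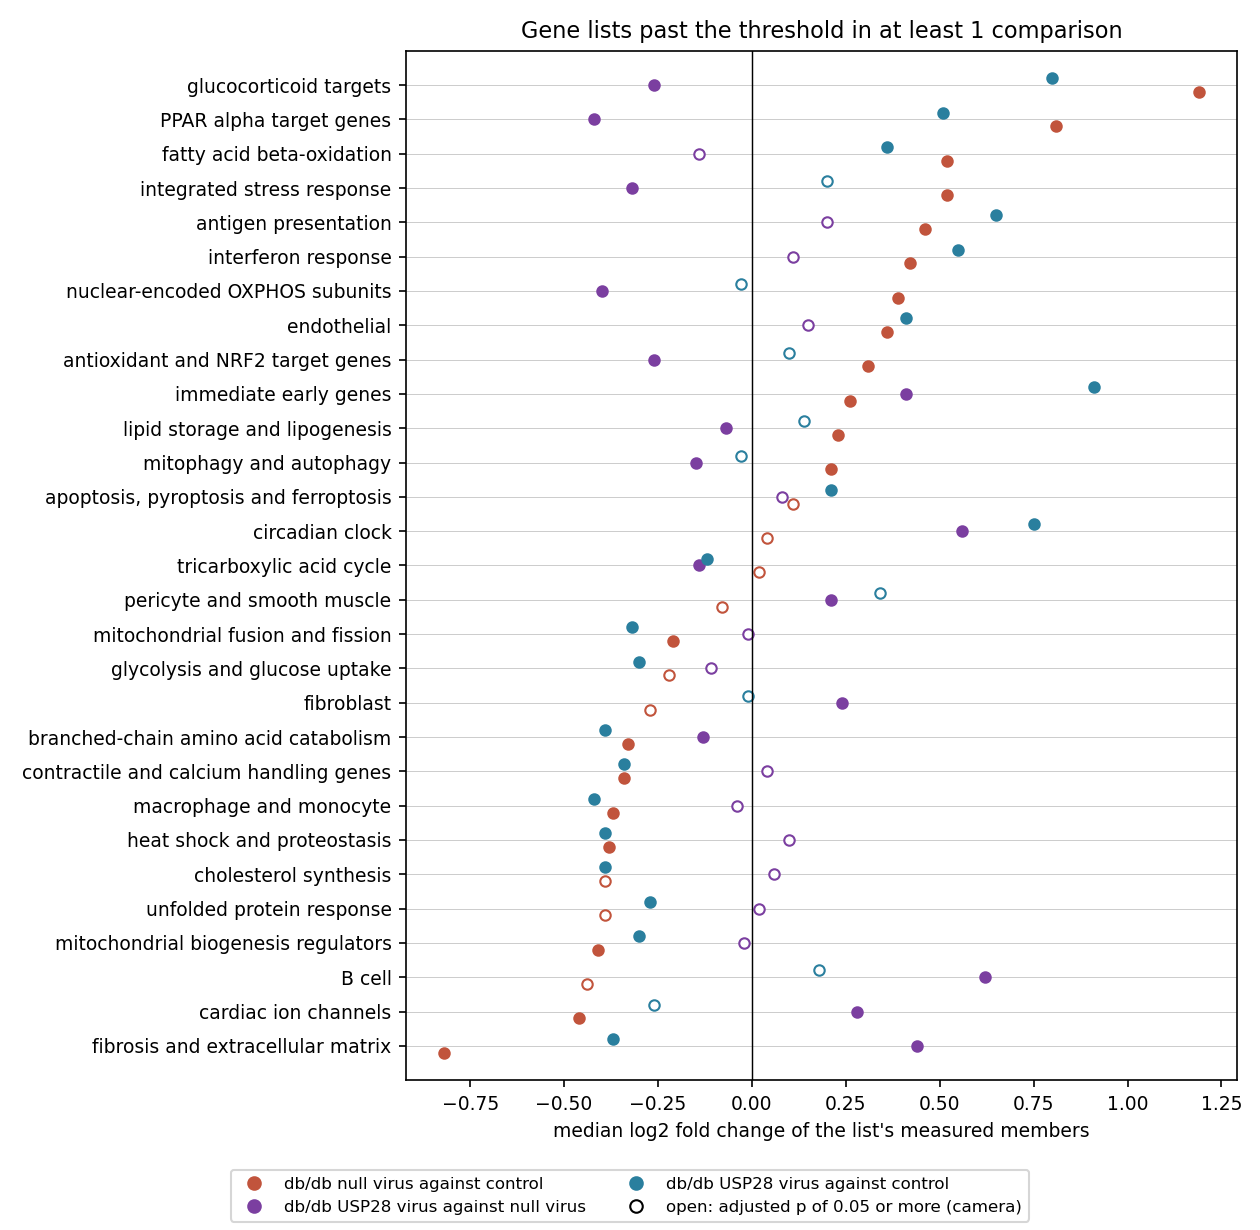
Median log2 fold change of the measured members of each gene list that passed camera in at least 1 of the 3 comparisons, with filled points where the adjusted p passed and open points where it did not. The matrix list was at -0.82 with null virus against control and at 0.44 with USP28 virus against null virus, and 0 of the lists passed with an estimated correlation.

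The comparison of USP28 virus with null virus in db/db hearts sets groups side by side that differ by label only in the USP28 vector. Usp28 itself did not pass between them. The labels do not give the time of tissue collection, which may differ too. Col15a1, Loxl2 and Myh7b were higher with USP28 virus, and Pdk4, Cdkn1a and Mt1 were lower. Myh7b, a slow-type myosin heavy chain (chromosome 2, 155611212 to 155634307), rose from 26.8 ± 5.48 to 75.6 ± 3.95 scaled RPKM (SD, n = 3; log2 1.51, SE 0.2, adjusted p = 0.03). Pdk4 fell from 727 ± 146 to 344 ± 13 (log2 -1.06, SE 0.16, adjusted p = 0.04). Of 14104 genes tested, 83 passed, 55 higher and 28 lower, and 2349 had an unadjusted p under 0.05. Groups did not overlap for 3288 genes (23.3%, against 10% by chance). The number passing rested on single libraries. It was 916 without null-virus replicate 1, with all 83 among them, and then 440 were higher and 476 lower. It was 0 in limma without null-virus replicate 2 or 3 or any USP28-virus library (1545 to 2754 at an unadjusted p under 0.05). In a limma fit of the 2 groups alone it was 0 (1772 at an unadjusted p under 0.05), with limma voom 187, and with library totals alone 31 (87.1% higher). Of the 351 genes in the lists that camera called, 10 passed, and 48 did so without null-virus replicate 1, 5, 1 and 2 without control replicates 1, 2 and 3, and 0 without any of the others. The number over all genes was 21, 9 and 10 without control replicates 1, 2 and 3, which enter through the shared estimate of the spread.

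Among the genes with the largest rises were Nr4a2, an orphan nuclear receptor of the immediate early class (log2 2.36, adjusted p = 0.043), Akap5, a scaffold for protein kinase A (log2 1.79), and Col15a1 (6.02 ± 0.72 against 1.98 ± 0.397, log2 1.56, adjusted p = 0.03). Lrrc15, a fibroblast membrane protein (log2 1.18), Loxl2, an enzyme that crosslinks collagen (log2 1.12), Lum (log2 1.01) and Krt222 (log2 1.11) rose as well. The matrix list had 4 of 33 members higher and 0 lower (17 higher adjusted over the list alone; adjusted p = 2.6e-08, and adjusted p = 0.38 with an estimated correlation). Col3a1 was at 5.51 ± 0.49 against 2.22 ± 0.87 (log2 1.34, adjusted p = 0.078) and Col1a1 at log2 -0.21 (adjusted p = 0.56), neither past the test. Col3a1 passed without null-virus replicate 1 (log2 1.61, adjusted p = 0.0095). Beside the matrix list, fibroblast markers had 1 of 13 members higher and 0 lower (4 higher adjusted over the list alone; adjusted p = 0.0084, and adjusted p = 0.46 with an estimated correlation). Pericyte and smooth muscle markers had 0 of 12 (2 higher adjusted over the list alone; median log2 0.21, adjusted p = 0.015, and adjusted p = 0.39 with an estimated correlation). B cell markers had 1 of 3 measured members higher (2 higher adjusted over the list alone; adjusted p = 0.043, and adjusted p = 0.44 with an estimated correlation), which was Blk, a B cell tyrosine kinase (1.02 ± 0.0268 against 0.199 ± 0.0492, log2 1.91). Without null-virus replicate 1 the fibroblast list had adjusted p = 0.092 and the pericyte and smooth muscle list 0.067 (median 0.12). The B cell list then had fewer than 3 measured members and was not tested. Its member Igkc passed the filter only through null-virus replicates 1 and 2 and USP28-virus replicate 2. Without each of these in turn the B cell median was 1.36, 1.36 and 1.22 over the members left, against 0.62 with all libraries. That median was 0.34 without null-virus replicate 3. Without USP28-virus replicate 1 the pericyte and smooth muscle list had 0.058 and the B cell list 0.065, and without null-virus replicate 3 the B cell list had 0.24. The matrix list had 10 higher and the fibroblast list 3 higher when null-virus replicate 1 was left out.

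Among the mitofusins, Mfn1 was at 43.8 ± 2.77 against 23.7 ± 1.73 (log2 0.89, adjusted p = 0.025) and Mfn2 at 68.2 ± 6.19 against 44.6 ± 1.1 (log2 0.61, adjusted p = 0.039). Without the values that are not whole numbers of reads, Mfn2 was at log2 0.57. Only null-virus replicate 1, which stood apart from its group, was then left with null virus, so the call of Mfn2 cannot be checked without them. Mfn1 could not be tested since all 3 of its null-virus values are of this kind. The fusion and fission list had 2 of 17 members higher, these 2, and 0 lower (2 and 1 adjusted over the list alone; adjusted p = 0.9). Ppara was at 2.05 ± 0.138 against 1.09 ± 0.469 (log2 0.93, adjusted p = 0.13), with 2 USP28-virus values that are not whole numbers of reads.

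Among the genes with the largest falls were Mt1, a metallothionein that binds zinc (7.75 ± 1.09 against 18 ± 1.92, log2 -1.21, adjusted p = 0.036), Cdkn1a (log2 -1.09, adjusted p = 0.031), Maff, a small MAF transcription factor (log2 -1.06), Pdk4, Trmt5, a tRNA methyltransferase (log2 -0.94), Art5, an ADP-ribosyltransferase (log2 -0.89), and Imp3, a nucleolar protein of ribosome assembly (log2 -0.87). Glucocorticoid targets had 3 of 15 members lower and 0 higher (5 lower adjusted over the list alone; adjusted p = 0.0018, and adjusted p = 0.38 with an estimated correlation), namely Mt1, Cdkn1a and Pdk4. The PPAR alpha target list had 1 of 18 members lower, Pdk4, and 0 higher (8 lower adjusted over the list alone; adjusted p = 8.8e-07, and adjusted p = 0.33 with an estimated correlation). Antioxidant genes had 1 of 28 lower, the glutathione transferase Gsta4 (60.3 ± 3.01 against 100 ± 6.74, log2 -0.73), and 0 higher (10 lower adjusted over the list alone; adjusted p = 3.8e-06, and adjusted p = 0.35 with an estimated correlation). Nuclear-encoded subunits of oxidative phosphorylation had 0 of 76 members past the test, and 0 adjusted over the list alone, at a median log2 difference of -0.40 (camera adjusted p = 6.9e-14, and adjusted p = 0.53 with an estimated correlation). That median was -0.13 without null-virus replicate 1. Without the same library the median moved from -0.26 to -0.17 for antioxidant genes and from -0.26 to -0.50 for glucocorticoid targets. Other lists with 0 members past the test were lower by camera. Mitophagy genes had a median of -0.15 (9 lower adjusted over the list alone; adjusted p = 4.8e-05, and adjusted p = 0.35 with an estimated correlation), the tricarboxylic acid cycle -0.14 (0 over the list alone; adjusted p = 0.0069, and 0.53 with an estimated correlation), and branched-chain amino acid breakdown -0.13 (0 over the list alone; adjusted p = 0.0097, and 0.39 with an estimated correlation). The integrated stress response list had a median of -0.32 (0 over the list alone; adjusted p = 0.013, and 0.35 with an estimated correlation) and lipid storage -0.07 (3 lower adjusted over the list alone; adjusted p = 0.025, and 0.38 with an estimated correlation). Without null-virus replicate 1 the median was -0.07 for the tricarboxylic acid cycle and -0.17 for lipid storage, and with library totals alone -0.06 and -0.02. Library totals alone also moved mitophagy to -0.07 and branched-chain amino acid breakdown to -0.06. Leaving out 1 library lost some of these calls. The tricarboxylic acid cycle (adjusted p = 0.062) and branched-chain amino acid breakdown (0.088) lost theirs without USP28-virus replicate 1. The integrated stress response list lost its call without null-virus replicate 1 (0.084) or USP28-virus replicate 2 (0.052), and lipid storage without null-virus replicate 2 (0.055) or 3 (0.079). Leaving out null-virus replicate 1 also gave 3 lower PPAR alpha targets, 5 lower antioxidant genes and 6 lower mitophagy genes. The median of glucocorticoid targets was -0.16 without USP28-virus replicate 2, and that of the tricarboxylic acid cycle -0.22 without null-virus replicate 2. Lipid storage had medians of -0.11 without control replicate 1, -0.13 without null-virus replicate 3, and -0.12, -0.13 and -0.13 without USP28-virus replicates 1, 2 and 3.

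Circadian clock genes had 0 of 18 members past the test (4 higher adjusted over the list alone) at a median of 0.56 (adjusted p = 0.00073, and adjusted p = 0.33 with an estimated correlation). Immediate early genes had 1 of 20 higher, Nr4a2, and 0 lower (4 higher adjusted over the list alone; adjusted p = 0.001, and adjusted p = 0.48 with an estimated correlation), and Nr4a1, a related receptor, was at log2 2.53 with adjusted p = 0.079. Ion channels had 0 of 20 past the test at a median of 0.28 (2 higher adjusted over the list alone; adjusted p = 0.02, and adjusted p = 0.53 with an estimated correlation). Their median was 0.11 without null-virus replicate 1 (adjusted p = 0.33). Nppa, Nppb, Myh7 and Myh6 were at adjusted p = 0.68, 0.38, 0.89 and 0.38. Nppa was at 1305, 147 and 172 scaled RPKM in USP28-virus replicates 1, 2 and 3, so its high mean there rested on replicate 1.

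Both comparisons use the null-virus libraries, which alone sets their fold changes against each other. Of the 83 genes that passed between USP28 virus and null virus, 63 also passed between null virus and control, 62 with the opposite sign and 1 with the same sign. Of the 62, 39 were lower with null virus and higher with USP28 virus, against 6.75 for independent lists, and 23 were the reverse, against 2.82. For the same sign, independent lists would share 5.54 higher and 3.44 lower genes. Krt222, Col15a1, Lum, Myh7b and Mfn1 were of the first kind and Ypel3, Gsta4 and Snrnp48 of the second. Mfn2 was of the first kind too. Both comparisons use the null-virus values, of which 3 of Mfn1 and 2 of Mfn2 are not whole numbers of reads. The place of the mitofusins among these genes therefore cannot be checked. Across all 14104 genes, which are not independent replicates, the correlation of the fold changes was -0.555, where simulated unchanged groups sharing those libraries gave -0.667 (SD 0.015 over 100 simulations). The covariance was -0.128 against a simulated -0.0732, a difference of -0.0547. In the 20 simulations for which calls were made, at most 16 genes passed in both comparisons with opposite signs. The 3 shared libraries are too few to split, so part of the excess may come from them. Without null-virus replicate 1 the count with opposite signs was 608, 304 of each kind, and with the same sign 29. It was 16, 7 and 7 without control replicates 1, 2 and 3, and 0 without null-virus replicate 2 or 3 or any USP28-virus library or in fits of 2 groups alone.

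**Figure D3:**
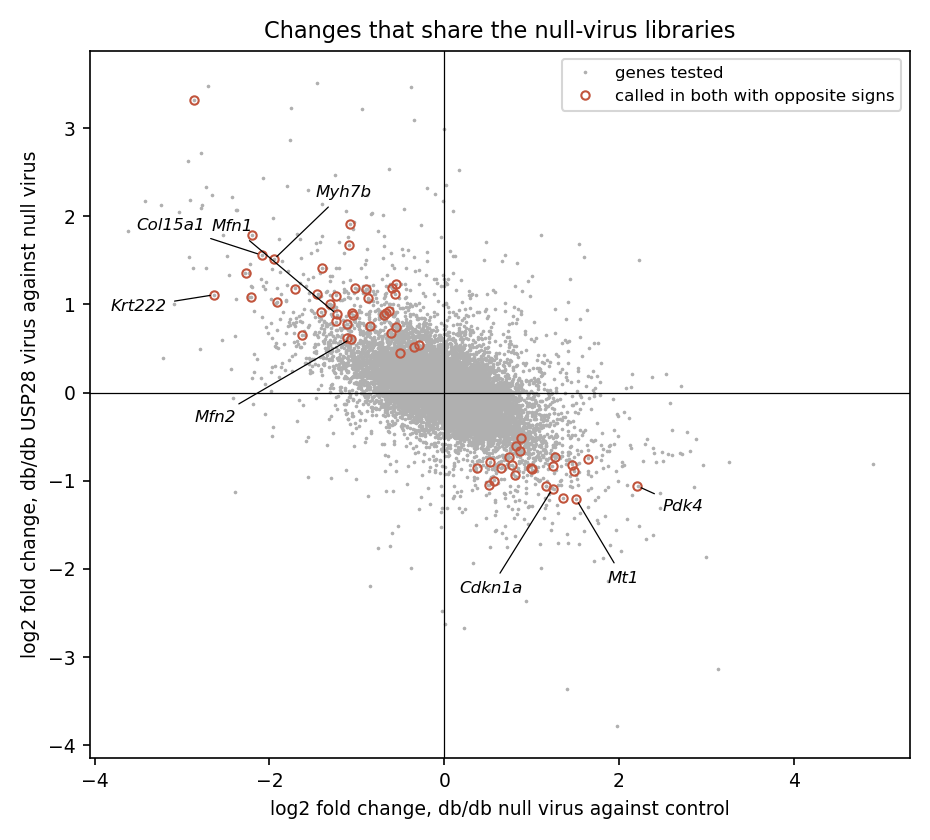
Log2 fold change of each tested gene with null virus against control (horizontal) and with USP28 virus against null virus (vertical), with circles for the genes that passed in both with opposite signs. The 62 circled genes lie at the upper left (39) and lower right (23), and the slope of the cloud contains the part set by the shared null-virus libraries.

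The comparison of USP28 virus with control addresses how far treated db/db hearts stood from wild-type hearts. Acot1, Per1 and Nr4a1 stood above control, and the ketone-using genes Bdh1 and Oxct1 under it. Acot1 was at 31.1 ± 4.4 against 5.78 ± 2.24 scaled RPKM (SD, n = 3; log2 2.47, SE 0.25, adjusted p = 0.0023). Bdh1 was at 5.42 ± 0.883 against 27.9 ± 2.21 (log2 -2.35, adjusted p = 0.0023), and Per1, a light- and glucocorticoid-induced clock gene (chromosome 11, 69095217 to 69109960), at 11.3 ± 0.941 against 2.2 ± 1.25 (log2 2.45, adjusted p = 0.0091). Of 14104 genes tested, 1659 passed, 793 higher and 866 lower, and groups did not overlap for 6445 (45.7%, against 10% by chance). The number passing was 1032, 460 and 448 without control replicates 1, 2 and 3, 361, 751 and 561 without USP28-virus replicates 1, 2 and 3, and 4111 without null-virus replicate 1, which is in neither group but enters the shared estimate of the spread. In a fit of the 2 groups alone it was 3839, and with library totals alone 921 (66.4% higher). Of the 387 genes in the lists that camera called here, 121 passed. That number was 52 and 57 without control replicates 2 and 3, 48, 67 and 66 without USP28-virus replicates 1, 2 and 3, and 215 without null-virus replicate 1.

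PPAR alpha targets had 8 of 18 members higher and 0 lower (13 higher adjusted over the list alone; adjusted p = 2.6e-08, and adjusted p = 0.33 with an estimated correlation), with Acot2 at log2 1.53. Beta-oxidation genes had 9 of 22 higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 1.5e-05, and adjusted p = 0.46 with an estimated correlation). Acadvl, very long-chain acyl-CoA dehydrogenase (479 ± 38.1 against 203 ± 16.1, log2 1.24), and Acadm, the medium-chain enzyme (597 ± 65.8 against 326 ± 20.9, log2 0.87), were among them. All 3 USP28-virus values of each are not whole numbers of reads. In USP28-virus replicate 2 Acadm alone held 108236 reads, where the column total left 95972 for all such values. In replicates 1 and 3 such values also held more than the totals left. Both rises may thus be overstated. The list has 4 members with such values. Inmt, an indolethylamine methyltransferase (log2 2.78), Nrxn2, a neurexin (log2 2.36), and Irs2, an insulin receptor substrate (2.91 ± 0.305 against 0.528 ± 0.211, log2 2.31), were among the largest rises. Immediate early genes had 10 of 20 higher and 0 lower (14 higher adjusted over the list alone; adjusted p = 5.8e-07, and adjusted p = 0.37 with an estimated correlation). They included Nr4a1 (log2 2.70), Nr4a2 (log2 2.37) and Klf2, an endothelial transcription factor (log2 1.77). Clock genes had 9 of 18 higher and 1 lower (11 and 2 adjusted over the list alone; adjusted p = 0.0011, and adjusted p = 0.34 with an estimated correlation). Per2, a partner of Per1, was at log2 1.91, and the 1 lower gene was Arntl, which encodes the activator BMAL1 (0.301 ± 0.0428 against 1.49 ± 0.866, log2 -1.78). Glucocorticoid targets had 8 of 15 higher and 0 lower (8 higher adjusted over the list alone; adjusted p = 3.8e-06, and adjusted p = 0.33 with an estimated correlation). Antigen presentation genes had 9 of 18 higher and 0 lower (12 higher adjusted over the list alone; adjusted p = 1.1e-07, and adjusted p = 0.38 with an estimated correlation). Interferon genes had 8 of 25 higher and 0 lower (10 higher adjusted over the list alone; adjusted p = 2.3e-07, and 0.39 with an estimated correlation). Endothelial markers had 5 of 14 higher and 0 lower (7 higher adjusted over the list alone; adjusted p = 0.00017, and 0.35 with an estimated correlation). Leaving out null-virus replicate 1, through the shared estimate of the spread, gave 15 higher and 2 lower beta-oxidation genes, 15 higher interferon genes and 9 higher endothelial markers.

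The largest falls were in S100a9, a calcium-binding protein of neutrophils (1.08 ± 0.616 against 12.4 ± 3.45, log2 -3.52, adjusted p = 0.003), Abat, the transaminase of GABA (log2 -2.82), and Acta1, skeletal actin (24.9 ± 6.92 against 149 ± 68.9, log2 -2.52, adjusted p = 0.011). Branched-chain amino acid genes had 9 of 22 lower and 0 higher (15 lower adjusted over the list alone; adjusted p = 6.3e-07, and adjusted p = 0.33 with an estimated correlation). Glycolysis had 6 of 26 lower and 1 higher (9 and 1 adjusted over the list alone; adjusted p = 6.7e-05, and adjusted p = 0.39 with an estimated correlation), with Hk2 at log2 -1.17. Fusion and fission genes had 6 of 17 lower and 0 higher (9 lower adjusted over the list alone; adjusted p = 4.3e-05, and adjusted p = 0.33 with an estimated correlation): Dnm1l, the fission GTPase, was at log2 -0.95, Opa1 at -0.75, Mfn2 at -0.46 and Mfn1 at -0.34. The call of Mfn1 was lost once the values that are not whole reads were left out (adjusted p = 0.062). All such values of Mfn1 are in null-virus libraries, outside this comparison, and its log2 stayed at -0.34. The p-value moved through the shared estimate of the spread. Contractile genes had 7 of 22 lower and 0 higher (10 lower adjusted over the list alone; adjusted p = 4.3e-05, and adjusted p = 0.35 with an estimated correlation), with Actc1 at -1.13 and Casq2 at -0.85. The matrix list had 5 of 33 lower and 1 higher (11 and 2 adjusted over the list alone; adjusted p = 0.0019, and adjusted p = 0.55 with an estimated correlation), with Col3a1 at -1.12 and Col1a1 at -1.03. Heat shock genes had 8 of 20 lower and 0 higher (12 and 1 adjusted over the list alone; adjusted p = 0.00017, and adjusted p = 0.53 with an estimated correlation). Macrophage markers had 1 of 12 lower and 0 higher (6 lower adjusted over the list alone; adjusted p = 0.0027, and adjusted p = 0.47 with an estimated correlation). Leaving out null-virus replicate 1 gave more lower genes in the lists for branched-chain amino acids (14), glycolysis (16), fusion and fission (10), the contractile machinery (13), matrix (13), heat shock (12) and macrophages (4).

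Of 204335 values above 0 in the table, 33 in 11 genes were not a whole number of reads. None of the 33 was in a control library, 13 were in null-virus and 20 in USP28-virus libraries. Their smallest departure from a whole number was 0.045 reads, against a largest departure of 0.0011 reads among the other values. The genes were Acadl, Acadm, Acadvl, Cpt1b, Dgat2, Hdac3, Mfn1, Mfn2, Ppara, Pparg and Slc27a1, of which 8 are in the 10 metabolic and mitochondrial lists that hold 231 of the 14104 tested genes (1.64%; Fisher's exact p = 7.3e-13). In the USP28-virus libraries these values came to 293578, 165585 and 258335 reads, where the column totals left 210544, 95972 and 188284 for them. In the null-virus libraries they came to 24406, 16922 and 19471 reads, where the totals left 22972, 27451 and 33646. Most of those reads in null-virus replicates 2 and 3 were of Mfn1 (5842 and 6875) and Mfn2 (9042 and 10290). The totals there left more reads than these values held. The fall of the mitofusins with null virus, and their rise with USP28 virus, may thus be overstated. The totals do not say by how much for each gene. Without them Acadl moved from log2 0.85 (adjusted p = 0.011) to 0.55 with USP28 virus against control, with USP28-virus replicate 2 as the only library left in its group. Cpt1b, the muscle carnitine palmitoyltransferase, moved from 0.37 (adjusted p = 0.15) to 0.47 (adjusted p = 0.03) in the same comparison. Mfn1 lost its call with USP28 virus against control (adjusted p = 0.044 and then 0.062) and Hdac3, a histone deacetylase, with null virus against control (0.043 and then 0.068). Neither comparison holds such values of its gene, and the log2 changes stayed at -0.34 and 0.40. These p-values moved through the group outside each comparison, which enters the shared estimate of the spread. Acadm, Acadvl, Dgat2, Hdac3 and Pparg could then not be tested with USP28 virus, nor Mfn1, Dgat2 and Pparg with null virus. What made these values differ is not given in the sources used here.

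**Figure D4:**
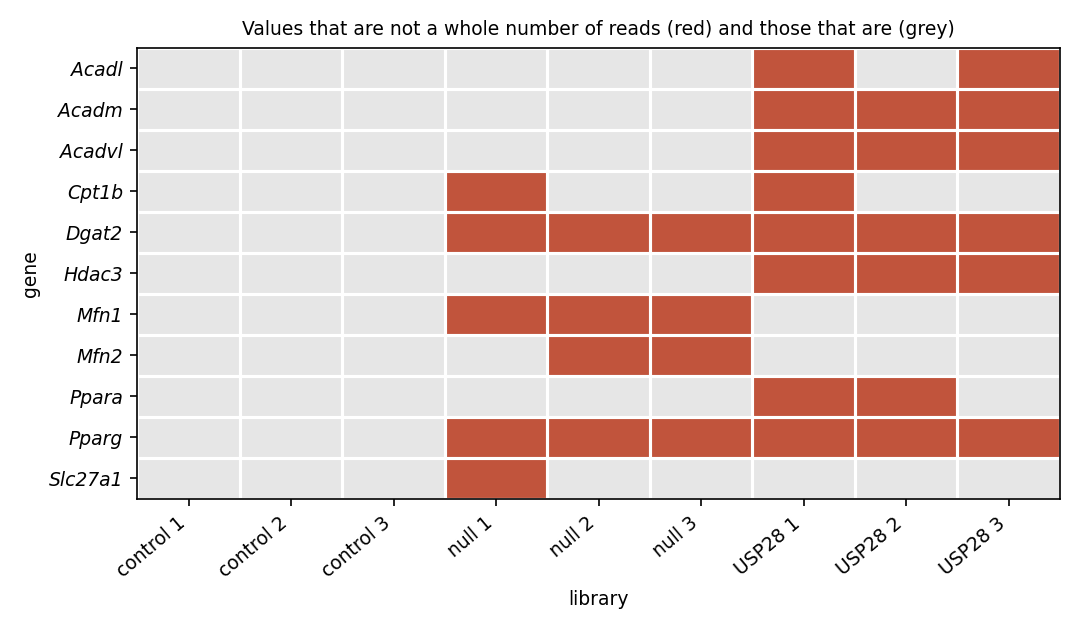
The 11 genes with values that are not whole numbers of reads (red) in each of the 9 libraries. The 3 control columns hold 0 such values, the null-virus columns 13 and the USP28-virus columns 20.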

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

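The length and GC trend, the omission of values that are not whole reads and library totals for lists were chosen only after the result was seen. The median log2 of each called list kept its sign under every scaling. Of the calls of named genes 0 were reversed, while genes that did not pass could change sign (Nppa with null virus against control, -0.08 to 0.97). Named genes were not followed through the other filters, the fold threshold or the fit without mitochondrial genes. A setting that could not test a gene was skipped, as for Mfn1 in comparisons with null virus without the values that are not whole reads. Of the named genes that passed, 105 of 127 kept their call in each remaining setting with null virus against control. The numbers were 0 of 24 with USP28 virus against null virus and 57 of 109 with USP28 virus against control. In the same order, counts of genes passing were 2086, 10 and 908 with no filter, 1673, 0 and 3839 in fits of 2 groups alone, and 733, 33 and 318 at an absolute log2 change of at least 1. Between USP28 virus and null virus, 31 passed with library totals alone (87.1% higher, against 66.3%), 177 with a stricter filter and 187 with limma voom, and 84 with length and GC trends removed (54.8% higher). For USP28 virus against control, library totals alone gave 921 (66.4% higher, against 47.8%). The median log2 of all tested genes between USP28 virus and null virus was 0.086 with library totals alone, against 0.015. The replicate numbers do not pair the samples (residual correlations of 9 same-numbered pairs, -0.029 to 0.06), and with the replicate block 2777, 0 and 1298 genes passed, the 0 in limma with 2336 at an unadjusted p under 0.05. The limma fit of 2 groups alone that gave 0 had 1772 at an unadjusted p under 0.05. Counts with opposite signs were 24 with totals, 7 with no filter, 130 with the stricter filter, 0 with 2 groups alone, 0 under the replicate block, 134 with voom and 21 at an absolute log2 of at least 1 in both. Leaving out 1 library gave 1445 to 4465, 0 to 916 and 361 to 4111 genes, 0 to 608 opposite signs, and 20 to 21, 12 to 19 and 17 to 21 lists. With 1 library left out the log2 difference of Usp28 ranged from -0.77 to -0.59, 0.29 to 0.49 and -0.33 to -0.22, and with length and GC trends removed the first was -0.53. For the other two it passed without null-virus replicate 1 (0.49, adjusted p = 0.015, and -0.29, adjusted p = 0.021), and against control in 2 groups alone (-0.28, adjusted p = 0.033). With an estimated correlation 0, 0 and 0 lists passed, and fry passed 10 between USP28 virus and null virus. The MYC and ribosome biogenesis list, lower and not past the threshold between USP28 virus and null virus, was higher without null-virus replicate 1 (adjusted p = 0.015; 0.67 without USP28-virus replicate 2). The cause was not tested for these changes. The DESeq2 alternatives were not run. With 3 libraries per group, genes changed 1.5-fold were mostly missed in simulated data, so genes that did not pass are not shown to be unchanged.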

Other observations

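The tests of a length and GC trend, of a USP28-virus library under another label, of the values that are not whole reads, of clock genes and of chromosome windows were chosen only after the result was seen.

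Further groups moved in the comparison of USP28 virus with control. The unfolded protein response had 2 of 21 members lower and 0 higher (4 lower adjusted over the list alone; adjusted p = 0.0025, and adjusted p = 0.58 with an estimated correlation). Pdia4, a protein disulfide isomerase, was at log2 -0.80 and Sdf2l1, an endoplasmic reticulum chaperone component, at -1.94. Cholesterol synthesis had 1 of 14 lower, Hmgcs1, the cytosolic HMG-CoA synthase (log2 -0.49), and 0 higher (1 lower adjusted over the list alone; adjusted p = 0.042, and adjusted p = 0.35 with an estimated correlation). Mitochondrial biogenesis regulators had 3 of 17 lower and 0 higher (3 lower adjusted over the list alone; adjusted p = 0.0026, and adjusted p = 0.38 with an estimated correlation). These were Esrrg, an orphan nuclear receptor (log2 -0.70), Twnk, the mitochondrial DNA helicase (log2 -0.63), and Tfam, the mitochondrial transcription factor (log2 -0.44). The tricarboxylic acid cycle had 4 of 20 lower and 0 higher (7 lower adjusted over the list alone; adjusted p = 0.034, and adjusted p = 0.62 with an estimated correlation). They included Dlst and Dld, subunits of the 2-oxoglutarate dehydrogenase complex (log2 -0.59 and -0.51), and Pcx, pyruvate carboxylase (log2 -1.28). Cell death genes had 3 of 19 higher and 0 lower (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.35 with an estimated correlation): Gsdmd, the pore-forming protein of pyroptosis (log2 0.80), Bcl2l1, an inhibitor of apoptosis (log2 0.80), and Ripk1, a kinase of necroptosis (log2 0.58). Leaving out null-virus replicate 1 gave 6 lower genes of the unfolded protein response, 3 of cholesterol synthesis, 8 lower and 1 higher biogenesis regulators, 9 lower and 3 higher tricarboxylic acid cycle genes, and 8 higher and 1 lower cell death genes. Some of these calls were lost when 1 library was left out. The unfolded protein response had adjusted p = 0.063 without control replicate 3 (median -0.09, against -0.27), and a median of -0.45 without control replicate 1. The tricarboxylic acid cycle had 0.087 without control replicate 3, and 0.068 and 0.066 without USP28-virus replicates 1 and 2. Cholesterol synthesis had 0.07, 0.092 and 0.075 without control replicates 1, 2 and 3, 0.062 and 0.058 without null-virus replicates 1 and 3, and 0.065 and 0.06 without USP28-virus replicates 1 and 3.

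Immediate early genes were also higher with null virus against control, with 5 of 20 members higher and 0 lower (6 higher adjusted over the list alone; adjusted p = 0.023, and adjusted p = 0.59 with an estimated correlation), including Klf2 (log2 1.53) and Klf4, a related Krueppel-like factor (log2 1.36). Without control replicate 1 the immediate early list had adjusted p = 0.29 (median 0.04, against 0.26), and without control replicate 3 its median was 0.44. Insulin and IGF signalling did not pass as a list, with 1 of 21 higher and 4 lower (1 and 4 adjusted over the list alone; adjusted p = 0.27). Akt1, the kinase, was at log2 -0.52 and Igfbp3, an IGF binding protein, at 0.85. A strain difference between db/db and control mice was looked for as clusters of changed genes along the chromosomes. Of 524 windows of 5 Mb, 0 had an excess of the 1235 genes called in the same direction in both db/db groups against control, with a smallest adjusted p of 0.78. A strain difference spread over the genome would leave no such window, so this count cannot exclude one.

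Null-virus replicate 1 stood apart from the other null-virus libraries, and the number of genes passing between USP28 virus and null virus was 916 without it and 83 with it. A trend with gene length and GC (Spearman -0.31 with length) is not the whole cause, since 84 genes passed once it was removed. RNA added from another cell type is argued against for the 6 types other than cardiomyocytes with at least 5 measured markers, whose highest median departure was 0.41 on the log2 scale (lowest -0.45), and a control library under its label by its position of 0.83 on the axis from control (0) to the other null-virus libraries (1). As the whole cause of its standing apart, a USP28-virus library under a null-virus label is argued against by Spearman correlations over the tested genes. Null-virus replicate 1 correlated at 0.932 to 0.939 with the USP28-virus libraries, which correlated at 0.973 to 0.975 with each other. It correlated at 0.935 with the other null-virus libraries. Whether its label is right could not be decided. It lay at 0.64 on the axis from the other null-virus libraries (0) to the USP28-virus libraries (1), and the control libraries lay at 0.78 to 0.83. Atrial cardiomyocyte markers were lower in null-virus replicate 1 (median -0.66 over 9 markers) and ventricular cardiomyocyte markers higher (median 0.42 over 16, from -1.52 to 1.26). Neither a difference in dissection nor a biological difference of that sample was tested.

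The 33 values that are not whole reads may come from a step applied to those values after the columns were scaled to a common total, since in 9 of 9 columns a departure from that total by more than 10 reads goes with the presence of such values. A rule acting on a whole gene is argued against by the 0 such values in control, decimals lost in printing by the smallest departure of 0.045 reads, and a random draw of genes by the Fisher's exact p of 7.3e-13. What the step was stays open, and no biological explanation was tested.

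The clock list was higher by camera with USP28 virus than with null virus (adjusted p = 0.00073, and adjusted p = 0.33 with an estimated correlation) with 0 of 18 members past the gene test, and the time of tissue collection is a candidate explanation. Across the 18 clock genes, which are not independent, that change went with the departure of control replicate 1 from the other controls (Pearson r = 0.9, Spearman 0.93), where the 95th percentile of 10000 random lists was 0.59 and 5 of those lists reached the observed 0.9. Random lists lack the shared regulation of clock genes, so any other shift of the clock could exceed them too, and r does not single out collection time. A length and GC trend is argued against by camera on the clock list once the trend was removed. Its adjusted p was then 0.0014 with USP28 virus against null virus and 0.00098 against control. An effect of USP28 virus or of db/db on the clock stays open and was not tested apart from collection time.

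With 3 libraries against 3 there are 10 splits, so the design cannot give a share under 0.1, and 1 of the 10, the real one, called as many genes in each comparison. The real splits called 3152, 83 and 1659 genes in limma and the highest of the others 0, 0 and 0, with at most 1258, 1337 and 395 at an unadjusted p under 0.05.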
